A study of Mus musculus with 12 samples.

How the data were processed

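RNA-seq libraries were made from liver of male C57BL/6 mice, an inbred laboratory strain, and 12 libraries in 4 groups of 3 were analysed here. Per the labels' protocols, mice entered the study at 6 weeks of age on a normal diet (NC) or a high-fat diet (HFD). After 8 weeks part of the high-fat group began exercise, named AE or RE, which lasted at least 12 weeks on the same diet (HFD+AE and HFD+RE). The labels give AE and RE only as abbreviations; in exercise studies they usually stand for aerobic and resistance exercise. The library numbers follow the labels: NC 2, 4 and 5, HFD 1, 2 and 3, HFD+AE 1, 2 and 3, and HFD+RE 3, 4 and 5. Nothing in the sources used here says that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

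The values are whole-number read counts per gene, deposited by the authors as 1 table without normalization. Counting used featureCounts 2.0.6, per the file headers. Per the submitters' processing notes, the other tools were fastp, HISAT2 2.2.1 and DESeq2 1.40.1, with the mm10 build of the mouse genome. Counting per gene sums reads over a gene's exons, so the values do not tell isoforms apart. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Genes of near-identical families (among them Mup, the Cyp2a, 2b, 2c, 2d, 2j, 3a, 4a and 4f subfamilies, Serpina1, Ces, Hsd3b, Ugt, Saa, Orm, Gst and the mitochondrial genes) can share reads with their copies, and their single values are uncertain. Genes that overlap a gene on the other strand are uncertain for the same reason.

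The table held 55291 genes, and the total count per library ran from 44373214 to 77665729. No pair of the 12 libraries agreed within sampling noise: the smallest chi-square per degree of freedom between 2 libraries was 82.4 over 12997 genes, so all 12 were counted as separate samples. Gene length came from the table. GC content came from a reference annotation (GENCODE M21) that shared 53292 gene names with the table, 52905 of them at the same coordinates, and 98.1% of the tested genes had a value.

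Genes were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F-test with robust dispersion, TMM scaling and its default low-count filter by group, which left 18305 genes (13786 of them protein coding in the reference). All 12 libraries entered 1 model with a mean per group, so that the 4 groups shared an estimate of the spread. A gene was called at a Benjamini-Hochberg (BH) adjusted p below 0.05 over the genes tested, and every adjusted p of a gene is from this test unless DESeq2 is named. Levels are CPM (counts relative to the library total after TMM scaling), given as mean ± SD over 3 libraries. Log2 changes come from the fitted model, with their standard error (SE).

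A set of 39 gene lists, covering liver functions and markers of other cell types, was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera asks whether a list ranks higher or lower than the other genes. The 36 lists with at least 5 tested members were adjusted together. With a correlation estimated for each list, none of the camera calls held in any of the 4 comparisons; the smallest adjusted p was then 0.27 for HFD vs NC, 0.28 for HFD+AE vs HFD, 0.12 for HFD+RE vs HFD and 0.59 for HFD+RE vs HFD+AE. At an unadjusted p under 0.05, 2, 5, 8 and 2 lists passed with the estimated correlation.

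The design, the gene lists, the first set of alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each of 4 comparisons, up to 8 genes that rose and 8 that fell with the largest log2 change. They had to pass the threshold, not overlap between the groups, have a mean log2 CPM above 1 and carry a symbol that is not a predicted or clone name. It added up to 3 called members of each list by smallest p, and 20 genes whether called or not, of which 1 is not reported (Cyp7a1, Cyp8b1, Srebf1, Fasn, Scd1, Cd36, Plin2, Cidea, Cidec, Pparg, Ppara, Cpt1a, Fgf21, Pck1, Igf1, Col1a1, Tnf, Saa1 and Trem2). The text gives values for part of the genes the rule took, mostly those called in every alternative, and that choice was made after their values were seen. Outside the rule, also chosen after their values were seen, are the 3 predicted genes of HFD+AE vs HFD, the genes other than Scd1 in HFD+RE vs HFD+AE, and those of the comparisons of the exercise groups with NC.

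Both exercise groups were compared with the same HFD libraries, which also entered HFD vs NC. The share of diet-called genes that moved back, and the correlation of the exercise effects, were therefore set beside 100 simulated data sets in which the exercise groups did not differ from HFD. Overlaps of calls were set beside simulations of the same kind, unchanged from HFD or, for comparisons with NC, unchanged from NC, in which as many genes per direction as were called were taken by smallest p from limma. All these simulations took the observed NC and HFD means, noise included, as the true ones. The simulated shares and overlaps may therefore be too low. The procedures were tested on simulated data drawn from the real means and library sizes. For HFD vs NC, over 17752 genes, 40% of genes changed 2-fold, 91.9% of those changed 4-fold and 98.5% of those changed 8-fold were recovered, with 12 false calls among 164. For HFD+AE vs HFD, over 17779 genes, the shares were 29%, 81.8% and 100%, with 5 false calls among 146. For HFD+RE vs HFD, over 17796 genes, they were 32.9%, 92.7% and 97.3%, with 1 false call among 148. In a simulation of each of these 3 comparisons, camera called the shifted list and no other list of the 36. The simulated genes were drawn independently of each other, while the correlations estimated in the real lists ran from 0.05 to 0.84. The simulations therefore do not show how often camera calls a list falsely in these data. They also held no library apart from its group, so the shares recovered and the false calls of single genes may differ in the real data. In the real HFD+AE vs HFD, Cfd, with a log2 change of -4.61, was not called (adjusted p = 0.052).

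Alternatives fixed in advance were DESeq2 1.42.0, RLE size factors, no low-count filter, a fit of only the groups compared, an added 2-fold threshold, an estimated inter-gene correlation, a replicate block for HFD and HFD+AE, and leaving out each library in turn. Another 3 were chosen after seeing the data: removal of each library's trend on gene length and GC content, removal of the trend on gene length alone, and leaving out HFD+AE 3 and HFD+RE 3 together. The length and GC trends were fitted as splines over 11062 genes with a mean log2 CPM above 1. Lists were not recomputed with DESeq2 or without the low-count filter. For single genes and single lists, the libraries left out in turn were those of the groups compared; for the counts of called genes, all 12 were. Limits for a count of 0 use 3 counts over the group and, like all counts here, cover counting error only.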

Results

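Liver transcripts were counted in 12 libraries from mice on a normal diet (NC), a high-fat diet (HFD), and a high-fat diet with AE or RE exercise (HFD+AE, HFD+RE), with 3 libraries in each group. Total counts ran from 47823607 to 77665729 in NC, from 44373214 to 60308552 in HFD, from 55922691 to 65434486 in HFD+AE and from 51178332 to 61089139 in HFD+RE. Of 55291 genes, 18305 had counts high enough to test. Alb, the gene of serum albumin, was the most abundant transcript in each of the 12 libraries, at 4.25% to 9.82% of the counts.

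The first principal component of log2 CPM held 40.6% of the variance and the second 14%. On the first, the NC libraries lay at -61.1, -72.7 and -40.2 and the HFD libraries at 67.4, 23 and 80.8. HFD+AE 1 and 2 lay at -40.4 and -36.9 and HFD+RE 3 at -36.6, all on the NC side. HFD+AE 3, at 14, and HFD+RE 4 and 5, at 50.4 and 52.6, lay on the HFD side, so 1 library of each exercise group stood apart from the other two of its group. Measures of the RNA mostly moved along the same axis. The share of counts from the mitochondrial rRNA genes was 1.76% to 3.26% in HFD and 0.708% to 0.924% in NC. It was 0.867%, 0.771% and 0.842% in HFD+AE 1, 2 and 3, and 0.685%, 1.11% and 1.71% in HFD+RE 3, 4 and 5. HFD+AE 3, on the HFD side of the component, thus had a share within the NC range. The rank correlation across genes between a library's level and gene length was 0.08 to 0.21 in NC and -0.29 to -0.15 in HFD. It was 0.29, 0.29 and -0.03 in HFD+AE 1, 2 and 3, and 0.22, -0.29 and -0.31 in HFD+RE 3, 4 and 5. The rank correlation with GC content was -0.21 to -0.13 in NC and -0.07 to 0.06 in HFD. In HFD+AE 1, 2 and 3 it was -0.29, -0.24 and 0.49, and in HFD+RE 3, 4 and 5 -0.22, 0.33 and 0.18. HFD+AE 3 also lay at -70.7 on the second component. The labels give no batch or date, so a batch that follows the groups cannot be told apart from them.

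**Figure D1:**
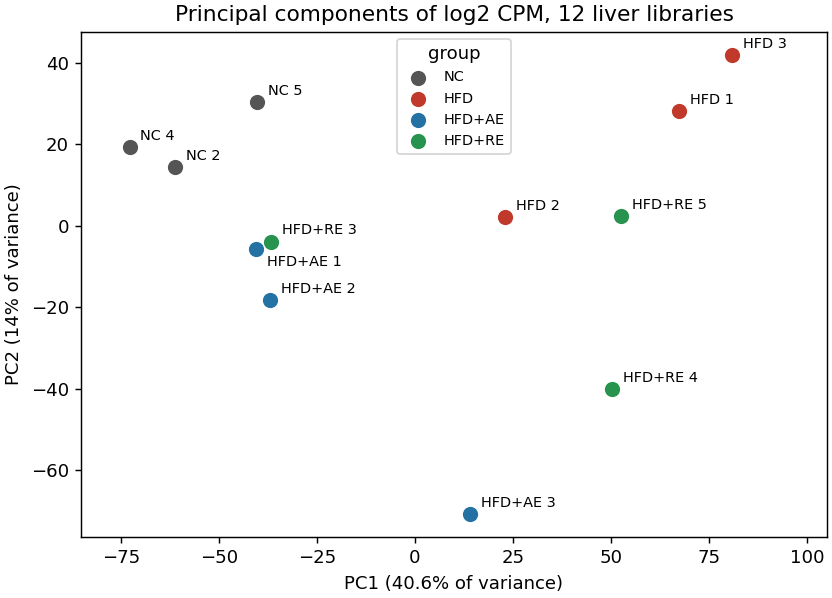
Principal components 1 and 2 of log2 CPM over the tested genes, 1 point per library and 1 colour per group; the axes give the component scores and the share of variance. HFD+AE 3 and HFD+RE 3 lie away from the other libraries of their groups along the first component.

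The comparison HFD vs NC asked how the high-fat diet changed liver transcripts. Hsd3b5, a hydroxysteroid dehydrogenase isoform found mainly in male mouse liver, fell from 163 ± 65.1 CPM (SD, n = 3) in NC to 0.346 ± 0.0749 CPM (SD, n = 3) in HFD, a log2 change of -8.88 (SE 0.83, adjusted p = 0.00024). Cyp2b9, a cytochrome P450 expressed mainly in female liver, rose from 1.0 ± 0.535 to 257 ± 24.9 CPM (log2 change 7.99, adjusted p = 0.0039). Themis, best known for its part in T-cell selection, rose from 0.795 ± 0.171 to 24.3 ± 3.21 CPM (4.92, SE 0.30, adjusted p = 5.3e-06). Cidec, which promotes the growth of lipid droplets, rose from 8.37 ± 2.68 to 34.4 ± 12.7 CPM (2.04, SE 0.28, adjusted p = 0.0022). Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, fell from 6950 ± 2640 to 1640 ± 196 CPM (-2.08, SE 0.35, adjusted p = 0.0049). Each of these 5 changes passed the threshold in every alternative.

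Over all 18305 genes, 2851 were called in HFD vs NC, of which 1534 rose and 1317 fell, and 6352 had an unadjusted p under 0.05. The values of the groups did not overlap for 46% of genes, where chance gives 10%. Among the genes called with the largest changes, Osbpl3, an oxysterol-binding protein, rose by 4.56 (SE 0.34, adjusted p = 4.1e-05), Sema5b, a semaphorin, by 3.81 (SE 0.41, adjusted p = 0.00064) and Rad51b, a DNA repair gene, by 4.24 (SE 0.64, adjusted p = 0.0034). On mm10, Hsd3b5 lies on chromosome 3 (98618634 to 98630252), Cyp2b9 on 7 (26173411 to 26210661), Themis on 10 (28668360 to 28883818), Cidec on 6 (113424634 to 113435760) and Scd1 on 19 (44394455 to 44407879). The count rested on single libraries: it was 488 without HFD 1, 411 without HFD 3, 941 without NC 2, 581 without NC 4 and 4462 without HFD+RE 3. It was 4928 when only these 2 groups were fitted, 1843 with a 2-fold threshold and 6258 without HFD+AE 3 and HFD+RE 3. Genes that rose were shorter (median 2445 bases) than those that fell (median 5277 bases), against 3548 bases over all genes tested.

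Most genes with higher expression in male than in female mouse liver fell. Of the 18 tested members of that list, 13 fell and 5 did not pass, and 13 fell when adjusted over the list alone. The median log2 change was -2.73 (camera adjusted p = 2e-09; adjusted p = 0.27 with an estimated correlation). C6, a component of the complement attack complex, fell from 383 ± 56.5 to 63.1 ± 21.6 CPM (-2.60, SE 0.34, adjusted p = 0.0016), and Cyp4a12b, a fatty acid hydroxylase, fell by 4.74 (SE 0.50, adjusted p = 0.00064). Mup1, a major urinary protein gene, changed by -7.84 (SE 1.49, adjusted p = 0.0089, and 0.056 without HFD 3). Its family has many near-identical copies, and the 22 Mup genes summed differed by -1.98 (SE 0.30) on the log2 scale. Moxd1 had no counts in HFD, and with Moxd1 set at the limit of 3 counts the median of the list was again -2.73. Female-biased liver genes went both ways: of 16 tested, 6 rose, 5 fell and 5 did not pass, with the same counts adjusted over the list alone (median 0.57, camera adjusted p = 0.31). Beside Cyp2b9, Hao2, a peroxisomal hydroxyacid oxidase, rose by 4.69 (SE 0.72, adjusted p = 0.0037), while Cyp3a44, another P450, fell by 3.62 (SE 0.52, adjusted p = 0.0027). Of 11 genes of the growth hormone and IGF axis, 1 rose, 2 fell and 8 did not pass, or 2 and 3 adjusted over the list alone (median -0.48, camera adjusted p = 0.24), and Igf1 stood at -0.06 (SE 0.28, adjusted p = 0.9).

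Part of the genes of lipid droplets and fatty acid uptake rose. Of 18 tested, 8 rose and 10 did not pass, and 8 rose adjusted over the list alone (median 0.74, camera adjusted p = 0.00085; adjusted p = 0.62 with an estimated correlation). Cidea, a lipid droplet protein related to Cidec, rose from 0.094 ± 0.0606 to 5.8 ± 1.32 CPM (5.84, SE 0.82, adjusted p = 0.0024), and Mogat1, an acyltransferase of triglyceride synthesis, rose by 3.66 (SE 0.53, adjusted p = 0.0027). Pparg, a nuclear receptor of fat storage, rose by 0.96 (SE 0.21, adjusted p = 0.014), a call lost without NC 4 (0.051) or HFD 1 (0.068). Cd36, a fatty acid transporter, rose by 1.43 (SE 0.40, adjusted p = 0.032), a call lost without NC 2 (0.11), NC 4 (0.11), HFD 1 (0.087), HFD 2 (0.078), HFD 3 (0.057) or the low-count filter (0.089). Plin2, a coat protein of lipid droplets, stood at 0.14 (SE 0.28, adjusted p = 0.74). In de novo lipogenesis, 2 of 20 genes rose, 3 fell and 15 did not pass, with the same counts adjusted over the list alone (median -0.36, camera adjusted p = 0.24). Beside Scd1, Acly, which makes acetyl-CoA from citrate, fell by 1.5 (SE 0.29, adjusted p = 0.0099, and 0.057 without HFD 3), and Fasn, the fatty acid synthase, stood at -0.30 (SE 0.46, adjusted p = 0.67). Of 23 cholesterol synthesis genes and SREBP2 targets, 5 fell and 18 did not pass, and 5 fell adjusted over the list alone (median -0.50, camera adjusted p = 0.0094; adjusted p = 0.69 with an estimated correlation). Cyp51, a demethylase of sterol synthesis, fell by 1.59 (SE 0.40, adjusted p = 0.024), a call lost without NC 2 (0.07), NC 4 (0.078), HFD 1 (0.063), HFD 3 (0.12) or the low-count filter (0.053).

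Of 30 genes of fatty acid oxidation and PPARA targets, 5 rose and 25 did not pass, and 5 rose and 2 fell adjusted over the list alone (median 0.12, camera adjusted p = 0.46). Fgf21, a hormone made by the liver, rose by 2.23 (SE 0.49, adjusted p = 0.015), a call lost without NC 2 (0.058), NC 4 (0.055), HFD 1 (0.058) or HFD 3 (0.077). Cpt1a, which controls fatty acid entry into mitochondria, stood at 0.15 (SE 0.25, adjusted p = 0.68). Of 20 genes of lipoproteins and LXR targets, 1 rose, 3 fell and 16 did not pass, or 2 and 3 adjusted over the list alone (median -0.09, camera adjusted p = 0.34). Oxidative phosphorylation was called higher (median 0.57 over 41 genes, camera adjusted p = 0.016; adjusted p = 0.69 with an estimated correlation), with 4 genes that rose and 37 that did not pass. None of its members passed when adjusted over the list alone, and the list's call was lost once each library's trend on length and GC content (0.14) or on length alone (0.2) was removed from HFD vs NC.

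Bile acid genes fell in part. Of 19 tested, 1 rose, 6 fell and 12 did not pass, or 2 and 9 adjusted over the list alone (median -0.47, camera adjusted p = 0.022; adjusted p = 0.62 with an estimated correlation). Cyp7b1, of the alternative pathway of bile acid synthesis, fell from 278 ± 73.3 to 40.8 ± 16.8 CPM (-2.77, SE 0.36, adjusted p = 0.0016), and Abcb11, the bile salt export pump, fell from 771 ± 120 to 254 ± 42.4 CPM (-1.60, SE 0.23, adjusted p = 0.0027). Cyp8b1, needed for cholic acid, rose by 1.44 (SE 0.36, adjusted p = 0.023), a call lost without NC 2 (0.053), NC 4 (0.054), NC 5 (0.055) or HFD 3 (0.085). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 0.27 (SE 0.95, adjusted p = 0.86). Without NC 5 it was 3.39 (adjusted p = 0.011), without NC 2 -0.23 and without NC 4 -0.29. In xenobiotic metabolism, 2 of 20 genes rose, 7 fell and 11 did not pass, or 3 and 8 adjusted over the list alone (median -0.43, camera adjusted p = 0.015; adjusted p = 0.62 with an estimated correlation). Cyp3a11, a major drug-metabolising P450, fell from 4590 ± 1310 to 526 ± 208 CPM (-3.13, SE 0.38, adjusted p = 0.0011), and Ces2a, a carboxylesterase, fell by 2.26 (SE 0.22, adjusted p = 0.00035).

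In amino acid catabolism and the urea cycle, 1 of 20 genes rose, 6 fell and 13 did not pass, or 2 and 8 adjusted over the list alone (median -0.43, camera adjusted p = 0.017; adjusted p = 0.62 with an estimated correlation). Cps1, the first enzyme of the urea cycle, fell from 4700 ± 305 to 969 ± 593 CPM (-2.28, SE 0.53, adjusted p = 0.018), a call lost without NC 4 (0.052), HFD 1 (0.086), HFD 3 (0.094) or the low-count filter (0.068). In the unfolded protein and integrated stress response, 1 of 20 genes rose, 8 fell and 11 did not pass, or 2 and 12 adjusted over the list alone (median -0.76, camera adjusted p = 0.005; adjusted p = 0.62 with an estimated correlation). Hyou1, a chaperone of the endoplasmic reticulum, fell by 1.86 (SE 0.37, adjusted p = 0.011), a call lost without HFD 1 (0.056) or HFD 3 (0.055). In gluconeogenesis and glucocorticoid response, 5 of 16 genes fell and 11 did not pass, and 5 fell adjusted over the list alone (median -0.49, camera adjusted p = 0.058). Pck1, which commits carbon to glucose synthesis, stood at -0.53 (SE 0.22, adjusted p = 0.11, and 0.043 without HFD+AE 3 and HFD+RE 3). Of 10 periportal genes, 2 fell and 8 did not pass, and 2 fell adjusted over the list alone (median -0.63, camera adjusted p = 0.039; adjusted p = 0.62 with an estimated correlation). That list's call in HFD vs NC was lost without NC 4 (0.089), HFD 1 (0.051) or HFD 3 (0.054), and without HFD+AE 3 and HFD+RE 3 (0.05). Of 12 pericentral genes, 1 rose and 1 fell over all genes and over the list alone (median 0.31, camera adjusted p = 0.34).

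A further 5 function lists were not called in HFD vs NC. Circadian clock genes had 2 of 19 that rose and 4 that fell, or 4 and 5 adjusted over the list alone, with a median of 0.14, a mean of -0.17 and a camera adjusted p of 0.75. NRF2 targets had 4 of 19 that rose and 1 that fell, or 4 and 2 adjusted over the list alone (median -0.04, mean 0.38, camera adjusted p = 0.9). Nqo1, a quinone reductase, rose by 1.48 (SE 0.25, adjusted p = 0.0051). The medians were -0.26 for 12 heat shock genes (camera adjusted p = 0.53), -0.05 for 24 cell cycle genes (0.74) and 0.12, with a mean of -0.11, for 16 immediate early genes (0.69).

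Part of the extracellular matrix genes rose. Of 23 tested genes of fibrosis and extracellular matrix, 8 rose and 15 did not pass, and 11 rose adjusted over the list alone (median 0.60, camera adjusted p = 0.0032; adjusted p = 0.62 with an estimated correlation). Dcn, a matrix proteoglycan, rose from 65.6 ± 5.51 to 171 ± 40.7 CPM (1.38, SE 0.20, adjusted p = 0.0027), and Col3a1, a fibrillar collagen, rose by 1.51 (SE 0.29, adjusted p = 0.0097). Col1a1, another fibrillar collagen, rose by 1.99 (SE 0.41, adjusted p = 0.012), a call lost without NC 4 (0.056) or HFD 1 (0.059). Stellate cell markers had 4 of 11 that rose and 7 that did not pass, and 5 that rose adjusted over the list alone (median 0.79, camera adjusted p = 0.0051; adjusted p = 0.62 with an estimated correlation). Among interferon-stimulated genes, 9 of 30 rose and 21 did not pass, and 14 rose adjusted over the list alone (median 0.50, camera adjusted p = 0.00035; adjusted p = 0.27 with an estimated correlation). Ifit3 and Isg15, both antiviral response genes, rose by 1.79 (SE 0.25, adjusted p = 0.0026) and 1.54 (SE 0.28, adjusted p = 0.0076). Of 19 cytokines, chemokines and adhesion molecules, 4 rose over all genes and over the list alone (median 0.26, camera adjusted p = 0.4). Il1rn, the antagonist of the interleukin-1 receptor, rose by 1.56 (SE 0.27, adjusted p = 0.0056). Tnf stood at 0.93 (SE 0.60, adjusted p = 0.28). Of 21 acute phase genes, 2 rose, 4 fell and 15 did not pass, or 3 and 4 adjusted over the list alone (median -0.10, mean 0.16, camera adjusted p = 0.7). Saa1, serum amyloid A, stood at 0.88 (SE 0.72, adjusted p = 0.4), and at 2.75 (adjusted p = 0.017) without NC 2.

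Markers of other cell types moved with the diet in both directions. Of 10 markers of B and plasma cells, 8 rose and 2 did not pass, and 9 rose adjusted over the list alone (median 1.93, camera adjusted p = 5.1e-05; adjusted p = 0.62 with an estimated correlation). Of 14 markers of T and NK cells, 4 rose and 10 did not pass, and 7 rose adjusted over the list alone (median 1.67, camera adjusted p = 0.0037; adjusted p = 0.62 with an estimated correlation). Of 13 markers of Kupffer cells and macrophages, 2 fell and 11 did not pass, and 3 fell adjusted over the list alone (median -1.03), while 3 of 12 endothelial markers fell, or 9 adjusted over the list alone (median -0.98). Both lists had a camera adjusted p of 0.0035 and an adjusted p = 0.62 with an estimated correlation. Cd163, a scavenger receptor of resident macrophages, fell by 2.52 (SE 0.55, adjusted p = 0.014), a call lost without HFD 1 (0.07), HFD 3 (0.079) or the low-count filter (0.057). The 8 neutrophil, 11 antigen-presenting cell, 12 lipid-associated and recruited macrophage, 7 cholangiocyte and 7 erythroid markers were not called (medians 1.57, 0.46, 0.73, -0.22 and 1.22; camera adjusted p = 0.058, 0.23, 0.15, 0.77 and 0.23). Trem2, a receptor of lipid-associated macrophages, stood at 0.72 (SE 0.52, adjusted p = 0.34). Over the markers of lymphocytes, the mean log2 CPM was 1.10, -0.20 and 1.92 in HFD 1, 2 and 3 and -0.82, -0.95 and -0.11 in NC 2, 4 and 5. The globin genes, whose transcripts come from red blood cells, moved along with them, at 6.05, 5.29 and 6.46 in HFD and 4.70, 3.32 and 5.61 in NC.

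Few members of the last lists were measurable. Of 7 adipocyte genes 3 were tested and 2 rose, or 3 adjusted over the list alone. Cfd, the complement protease adipsin, rose by 4.63 (SE 0.75, adjusted p = 0.0045) and stood at 9.77, 45 and 5.56 CPM in HFD 1, 2 and 3, with Adipoq at 0.082 CPM or less in each library. Of 11 skeletal muscle genes and 11 exocrine pancreas genes 1 each was tested, and neither passed (log2 change 0.60 and -1.68). The 5 sex chromosome genes were not called (median -0.61, camera adjusted p = 0.18), and Xist, which is expressed from the inactive X chromosome of females, stayed at 0.34 CPM or less in each library.

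**Figure D2:**
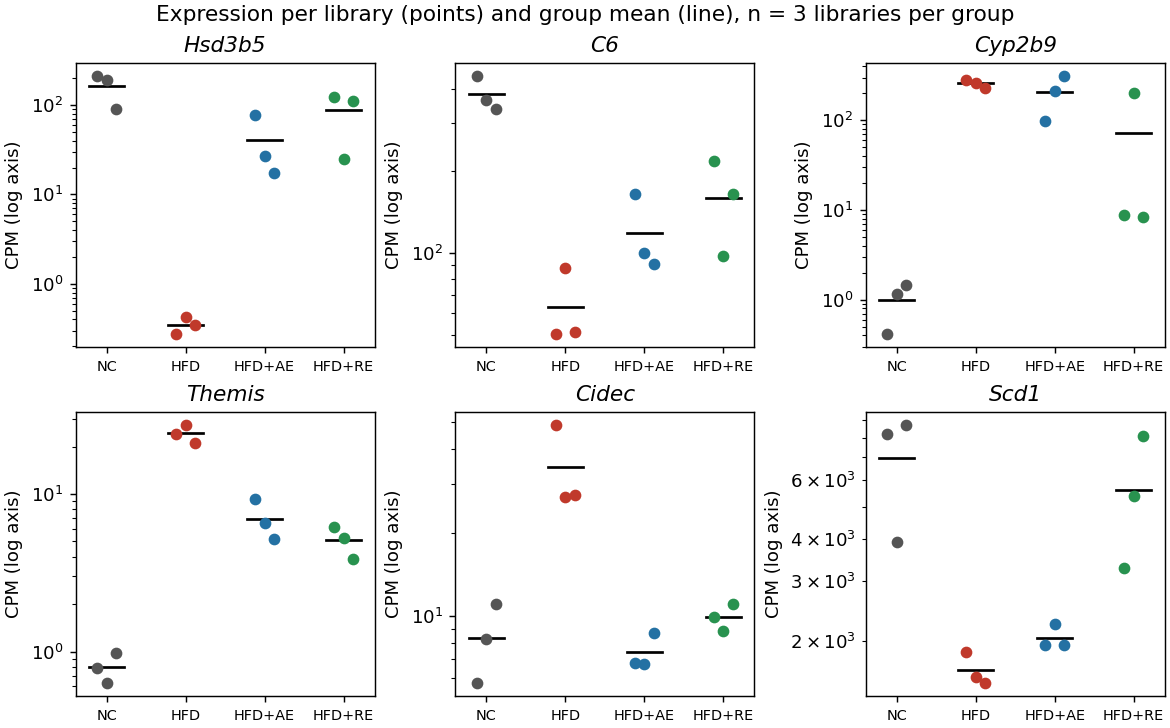
CPM of 6 genes in each library (points, logarithmic axis) and the mean of each group (lines), with 3 libraries per group. Hsd3b5 lies at 0.272 to 0.422 CPM in HFD and at 17.4 CPM or more in each library of the other groups, while Cyp2b9 stays high in HFD+AE.

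The comparison HFD+AE vs HFD asked what AE exercise changed on the high-fat diet. Hsd3b5 rose from 0.346 ± 0.0749 CPM (SD, n = 3) in HFD to 40.3 ± 32.1 CPM (SD, n = 3) in HFD+AE, a log2 change of 6.86 (SE 0.78, adjusted p = 0.011). Cidec, which promotes the growth of lipid droplets, fell from 34.4 ± 12.7 to 7.4 ± 1.14 CPM (-2.22, SE 0.28, adjusted p = 0.022), and Themis, known from T-cell selection, fell from 24.3 ± 3.21 to 6.99 ± 2.07 CPM (-1.80, SE 0.25, adjusted p = 0.038). Cyp2c54, a drug-metabolising P450, rose by 1.87 (SE 0.29, adjusted p = 0.048) and Tgfbr3, a TGF-beta co-receptor, by 1.02 (SE 0.16, adjusted p = 0.047), while mt-Nd4l, a mitochondrial gene of respiratory complex I, fell by 2.36 (SE 0.34, adjusted p = 0.038). The other 3 of the 9 called genes were predicted genes that fell: Gm13577 (-1.92, adjusted p = 0.047), Gm9800 (-1.20, adjusted p = 0.047) and Gm47664, which had 87 counts in HFD and none in HFD+AE, at least 29.5-fold lower against a floor of 3 counts over the group.

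Of the 6 genes that fell, 6 had risen in HFD vs NC, and of the 3 that rose, 2 had fallen there (0.5 and 0.22 expected if independent). The same HFD libraries enter both comparisons: over 100 simulations of exercise groups unchanged from HFD, as many top-ranked genes gave a mean of 2.31 and 1.2 shared, with 2 and 41 simulations as large. Of the 20 genes named in advance, edgeR called Cidec, and Cidea stood at -4.05 (SE 0.72, adjusted p = 0.054), Saa1 at -1.96 (0.13), Cpt1a at 0.67 (0.12), Col1a1 at -1.22 (0.094) and Scd1 at 0.31 (0.57). Cidea was called by DESeq2 (8.9e-07), without the low-count filter (0.03), from these 2 groups alone (0.039), without HFD 2 (0.024), with the length and GC trend (0.044) or the length trend alone removed (0.05), and without HFD+AE 3 and HFD+RE 3 (0.0094). Col1a1 was called by DESeq2 (0.03) and without HFD+AE 3 and HFD+RE 3 (0.018), and Saa1 from these 2 groups alone (0.044). An unadjusted p under 0.05 was found for 4826 genes, and the groups did not overlap for 32% of genes, where chance gives 10%. The count of 9 was 1691 without HFD 2, 1930 without HFD+RE 3, 124 without HFD+RE 5 and 21 without HFD+AE 3. It was 2 without HFD 3, HFD+AE 1, HFD+RE 4 or NC 2, 1 without HFD+AE 2 or NC 4, and 0 by edgeR without HFD 1 (3083 genes at an unadjusted p under 0.05). DESeq2 called 2105 genes with all libraries; edgeR called 953 without the low-count filter, 649 from these 2 groups alone, 546 with the length and GC trend removed, 77 with the length trend alone removed and 4253 without HFD+AE 3 and HFD+RE 3. The call of Hsd3b5 was lost without HFD 1 (0.1) or HFD 3 (0.082), that of Cidec without HFD 1 (0.1), HFD+AE 1 (0.12) or HFD+AE 2 (0.18), and that of Themis without HFD 1 (0.15), HFD 3 (0.097) or HFD+AE 2 (0.18). Those of the other 6 genes were lost without HFD 1 (0.15 to 0.2), HFD 3 (0.17 to 0.25), HFD+AE 1 (0.14) or HFD+AE 2 (0.18), and that of Gm47664 also without HFD+AE 3 (0.056). Cyp2c54 was not called with RLE size factors (0.051), Gm9800 with either trend removed (0.11 and 0.13), or Gm13577 with the length trend removed (0.054).

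Camera called 17 of 36 lists in HFD+AE vs HFD, 11 higher and 6 lower, while single members mostly missed the threshold over all genes. Higher among the function lists were xenobiotic metabolism (median 0.73, camera adjusted p = 1.4e-05), bile acid synthesis and transport (0.67, 0.00014), amino acid catabolism and urea cycle (0.37, 0.00023), fatty acid oxidation and PPARA targets (0.36, 0.00063), cholesterol synthesis and SREBP2 targets (0.58, 0.00067), lipoproteins and LXR targets (0.51, 0.0018), gluconeogenesis and glucocorticoid response (0.60, 0.0024), male-biased liver genes (0.91, 0.0092) and circadian clock (0.23, 0.046). These 9 lists had an adjusted p = 0.28 to 0.51 with an estimated correlation. Over all genes, by edgeR, Cyp2c54 was the called member of 20 in xenobiotic metabolism and Hsd3b5 that of 18 male-biased genes; adjusted over the list alone, 10 and 3 rose, as did 9 of 19 bile acid genes, with 1 that fell. Adjusted over the list alone, 4 of 23 cholesterol genes, 4 of 20 lipoprotein genes and 3 of 16 gluconeogenesis genes also rose. Over the 5 male-biased genes set outside multi-copy families, the mean log2 CPM was 2.6, 1.85 and 1.97 in HFD+AE 1, 2 and 3. It was 1.61, 2.06 and 2.11 in HFD 1, 2 and 3 and 5.18, 4.52 and 3.42 in NC. HFD+AE and HFD overlapped in this score, which was chosen after the results had been seen. In HFD+AE vs HFD the clock's call was lost without HFD 1 (0.054), HFD 3 (0.058), HFD+AE 1 (0.051) or HFD+AE 3 (0.059) and with either trend removed (0.13 and 0.15), and the clock (0.078) and lipoprotein (0.084) calls without HFD+AE 3 and HFD+RE 3.

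Of the cell type markers, endothelial cells (median 1.06, camera adjusted p = 0.00013) and Kupffer cells and macrophages (0.83, 0.0018) were called higher. Markers of B and plasma cells (-1.67, 3e-05), T and NK cells (-2.27, 7.6e-05), neutrophils (-2.66, 0.00014), antigen-presenting cells (-0.97, 0.0062) and erythroid cells (-1.39, 0.046) were called lower, as were interferon-stimulated genes (-0.27, 0.0036). These 8 lists had an adjusted p = 0.28 to 0.51 with an estimated correlation. No member passed over all genes tested by edgeR, while 9 of 10 B and plasma cell markers, 11 of 14 T and NK cell markers, 5 of 8 neutrophil markers and 4 of 30 interferon-stimulated genes fell adjusted over the list alone, and 9 of 12 endothelial markers rose. In HFD+AE vs HFD the call of antigen-presenting cells was lost without HFD 1 (0.072). That of erythroid cells was lost without HFD 2 (0.074), HFD 3 (0.058), HFD+AE 1 (0.062) or HFD+AE 2 (0.13), with either trend removed (0.11 and 0.12) and without HFD+AE 3 and HFD+RE 3 (0.054). Over the markers of lymphocytes, the mean log2 CPM was -0.91, -1.08 and -0.16 in HFD+AE 1, 2 and 3. It was 1.1, -0.2 and 1.92 in HFD 1, 2 and 3, so HFD 2 lay within the HFD+AE range. The globin genes stood at 4.20, 3.36 and 5.66 on the log2 CPM scale in HFD+AE 1, 2 and 3, against 6.05, 5.29 and 6.46 in HFD, and the log2 changes of all genes correlated with gene length across genes (rho = 0.30).

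The comparison HFD+RE vs HFD asked the same of RE exercise. Hsd3b5 rose to 87.1 ± 53.9 CPM (SD, n = 3) from 0.346 ± 0.0749 CPM (SD, n = 3), a log2 change of 7.97 (SE 0.81, adjusted p = 0.003), and Themis fell to 5.08 ± 1.16 from 24.3 ± 3.21 CPM (-2.26, SE 0.26, adjusted p = 0.0063). These were the 2 genes called, both were among the 9 of HFD+AE vs HFD, and both moved against their change in HFD vs NC. Groups unchanged from HFD shared a gene as often in 18 (higher) and 24 (lower) of 100 simulations with HFD+AE vs HFD, and in 38 and 39 with HFD vs NC. Cidec stood at 9.96 ± 1.14 CPM (-1.79, SE 0.28, adjusted p = 0.064), Scd1 at 5580 ± 2410 CPM (1.77, SE 0.34, adjusted p = 0.16) and Col1a1 at 3.93 ± 0.656 CPM (-1.58, SE 0.41, adjusted p = 0.28), none of them called by edgeR. DESeq2 called all 3 (3.4e-06, 0.00013 and 0.019), and edgeR without the low-count filter called Cidec (3.8e-05) and Scd1 (0.0011). The calls of Hsd3b5 and Themis held when any 1 library of these groups was left out. Cidec was called without HFD 2 (0.044). The Hsd3b5 call was lost when HFD+AE 3 and HFD+RE 3 were left out together (7.64, adjusted p = 0.079). An unadjusted p under 0.05 was found for 1605 genes, and 14.1% of genes did not overlap, where chance gives 10%. The count of 2 was 53 without HFD 2, 7 without HFD+RE 4, 6 without NC 2, 3 without HFD+RE 3 or HFD+RE 5, 186 by DESeq2, 43 without the low-count filter, 9 with the length and GC trend removed, 4 with the length trend removed and 5 without HFD+AE 3 and HFD+RE 3.

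Camera called 23 of 36 lists in HFD+RE vs HFD. The 8 higher ones were male-biased liver genes (median 1.23, camera adjusted p = 1e-09), amino acid catabolism and urea cycle (0.46, 2.4e-08), cholesterol synthesis and SREBP2 targets (0.69, 1.1e-06), bile acid synthesis and transport (0.38, 0.00033), de novo lipogenesis (0.46, 0.00062), lipoproteins and LXR targets (0.34, 0.00093), periportal genes (0.30, 0.024) and xenobiotic metabolism (0.17, 0.044). Among the 15 lower ones were heat shock (-0.82, 4.1e-07), lipid droplets and fatty acid uptake (-0.42, 1.6e-05), cytokines, chemokines and adhesion molecules (-0.48, 8.8e-05), fibrosis and extracellular matrix (-0.42, 0.00017) and interferon-stimulated genes (-0.38, 2.3e-06). Markers of antigen-presenting cells (-0.82, 2.3e-06), T and NK cells (-2.04, 2.6e-06), B and plasma cells (-1.16, 2.4e-05), neutrophils (-0.97, 0.00029) and lipid-associated and recruited macrophages (-0.76, 0.0047) were lower too. The other 5 were immediate early genes (-0.14, 0.0045), cell cycle (-0.26, 0.012), NRF2 targets (-0.22, 0.016), unfolded protein and integrated stress response (-0.30, 0.021) and acute phase proteins (-0.16, 0.024). These 23 lists had an adjusted p = 0.12 to 0.58 with an estimated correlation. Apart from Hsd3b5 no member passed over all genes by edgeR, while DESeq2 called Cidec and Cidea (3.4e-06 and 0.0038) of the lipid droplet list, Scd1 (0.00013) of lipogenesis and Col1a1 (0.019) of the matrix list. Adjusted over the list alone, 4 of 18 male-biased genes, 4 of 19 bile acid genes and 3 of 20 amino acid genes rose, and 8 of 12 heat shock genes, 4 of 18 lipid droplet genes, 4 of 23 matrix genes and 11 of 14 T and NK cell markers fell. Over the 5 male-biased genes set outside multi-copy families, the mean log2 CPM was 3.45, 2.04 and 2.95 in HFD+RE 3, 4 and 5. It was 1.61, 2.06 and 2.11 in HFD 1, 2 and 3, so HFD+RE 4 lay within the HFD range.

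Several of the calls in HFD+RE vs HFD were lost when 1 library was left out, many of them for more than 1 choice of library. Without HFD+RE 5 the lists of lipogenesis (0.35), cytokines (0.061), NRF2 targets (0.054), acute phase proteins (0.35), the unfolded protein response (0.085), cell cycle (0.18) and recruited macrophages (0.085) were not called. Without HFD+RE 3 the unfolded protein response (0.066), acute phase proteins (0.061), immediate early genes (0.052), periportal genes (0.28) and xenobiotic metabolism (0.14) were not, nor without HFD+RE 4 xenobiotic metabolism (0.61) and cell cycle (0.05). Without HFD 1 the calls of xenobiotic metabolism (0.078), periportal genes (0.05) and recruited macrophages (0.11) were lost, without HFD 2 those of the unfolded protein response (0.83, with a median of 0.04) and acute phase proteins (0.97, with a median of 0.07), and without HFD 3 those of xenobiotic metabolism (0.16), cell cycle (0.16) and periportal genes (0.058). Removing the length trend ended the call of xenobiotic metabolism (0.063). Without HFD+AE 3 and HFD+RE 3, xenobiotic metabolism (0.17), the unfolded protein response (0.13), acute phase proteins (0.093), immediate early genes (0.1), periportal genes (0.34) and neutrophils (0.05) were not called. The mitochondrial rRNA share was 0.685%, 1.11% and 1.71% in HFD+RE 3, 4 and 5, and the globin genes stood at 4.76, 4.11 and 6.05 on the log2 CPM scale. The markers of lymphocytes had a mean log2 CPM of -0.47, -0.32 and 0.15 in HFD+RE 3, 4 and 5. HFD 2, at -0.2, lay within that range, while HFD 1 and 3 stood at 1.1 and 1.92.

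**Figure D3:**
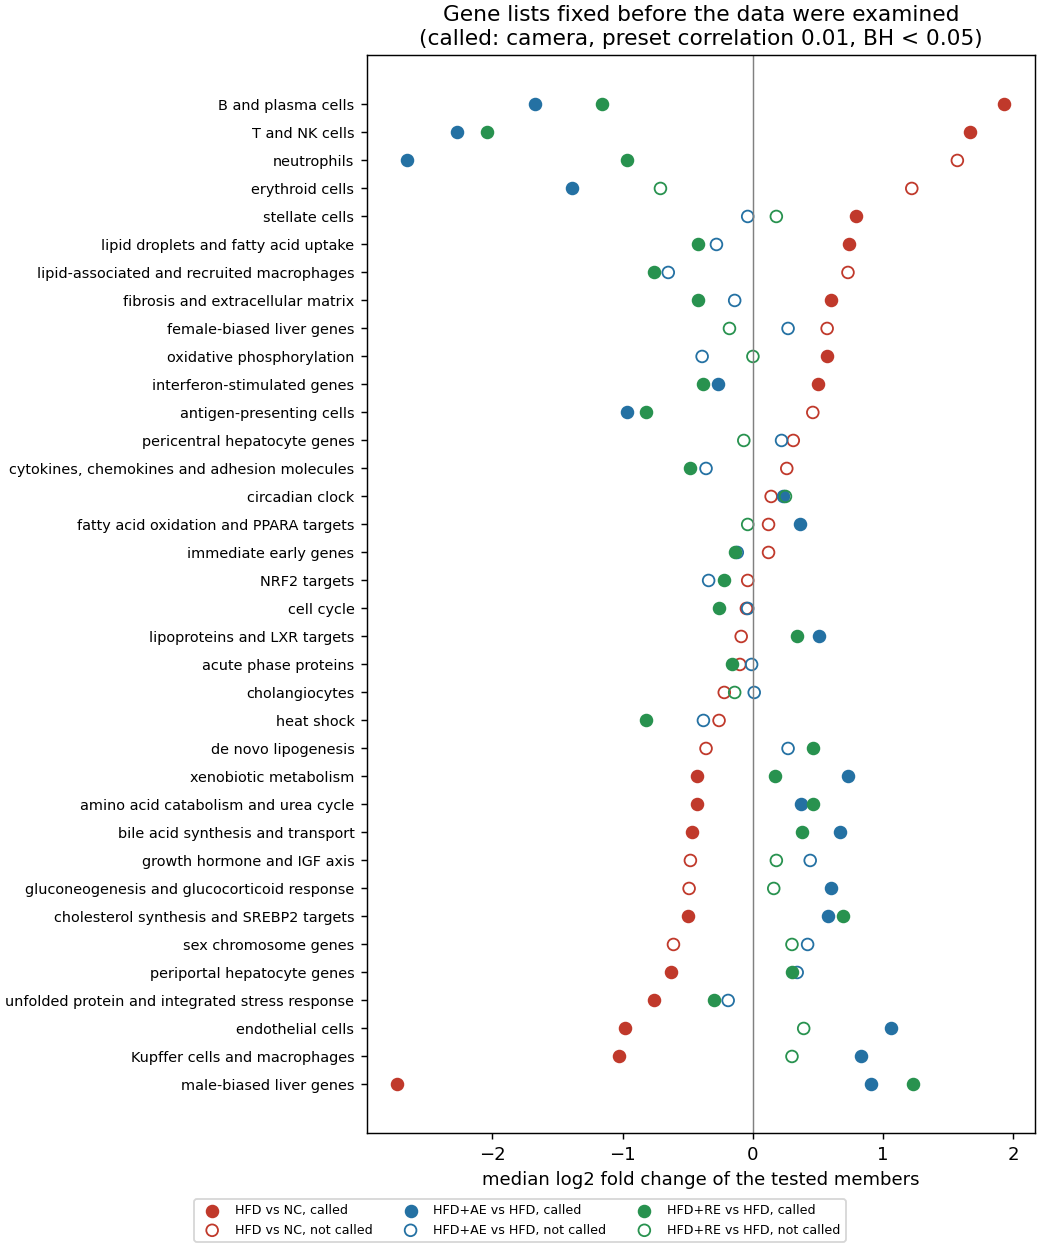
Median log2 change of the tested members of each gene list in HFD vs NC, HFD+AE vs HFD and HFD+RE vs HFD; filled points are lists called by camera with a preset correlation of 0.01, open points are not called. Male-biased liver genes lie at -2.73 with the diet and at 0.91 and 1.23 with AE and RE exercise. Part of that list belongs to multi-copy families, whose single values are uncertain.

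Set against the diet, the exercise groups moved mostly the other way. Of the 2851 genes called in HFD vs NC, 94.2% moved back in HFD+AE and 87% in HFD+RE. The same HFD libraries enter both sides, so unchanged groups also move back: the 100 simulated data sets gave a mean of 64.8% for HFD+AE (19.4% to 97.1%), 2 of them as large, and a mean of 62.9% for HFD+RE (18.1% to 97.2%), 15 of them as large. The simulations took the observed diet effect, noise included, as real, so the simulated shares may be too low and the counts of 2 and 15 too small. Without HFD 1 the HFD+AE share was 91.8%, with 8 of 100 simulated values as large, and without HFD 3 it was 92.2%, with 7. Without HFD+AE 3 and HFD+RE 3 the HFD+AE share was 95.3% and the HFD+RE share 54.8%. Across genes, which are not independent replicates, the effects of AE and RE correlated at r = 0.708, where unchanged groups gave a mean of 0.473 and 19 of 100 as large a value. Their covariance was 0.336 against a simulated mean of 0.1 and a highest simulated value of 0.32, a difference of 0.236. The covariance was 0.365 without HFD 1 (highest simulated 0.445, 2 of 100 as large), 0.616 without HFD 2 (highest 0.447), 0.313 without HFD 3 (highest 0.44, 4 as large) and 0.219 without HFD+AE 3 and HFD+RE 3 (highest 0.237, 1 as large). It was 1.03 without the low-count filter (highest 0.264). The correlation was 0.329 without HFD+AE 3 and HFD+RE 3, where unchanged groups gave a mean of 0.397 and 63 of 100 as large a value, and 0.564 without the low-count filter, with 40 of 100 as large.

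The comparison HFD+RE vs HFD+AE tested the difference between the exercise groups. Igfbp1, an IGF-binding protein that responds to insulin, stood at 14.1 ± 4.69 CPM (SD, n = 3) in HFD+RE and 86 ± 17.6 CPM (SD, n = 3) in HFD+AE (log2 change -2.61, SE 0.52, adjusted p = 0.52). Pdk4, which restrains glucose oxidation, stood at 1.79 ± 0.299 and 6.16 ± 0.551 CPM (-1.78, SE 0.37, adjusted p = 0.56), and Scd1 at 5580 ± 2410 and 2040 ± 174 CPM (1.45, SE 0.34, adjusted p = 0.61). Nr4a1, an immediate early nuclear receptor (-2.08, SE 0.40), and Zbtb16, a glucocorticoid-responsive transcription factor (-1.99, SE 0.40), both had an adjusted p of 0.52, and Hsd3b5 (1.11, SE 0.58) had 0.61. None of these differences passed, and edgeR called 0 genes, with 1468 at an unadjusted p under 0.05 and 24 called by DESeq2, among them Igfbp1 (0.00066), Pdk4 (0.0062), Nr4a1 (0.0012), Zbtb16 (0.0023) and Scd1 (0.016). The groups did not overlap for 11.3% of genes, where chance gives 10%. The edgeR count was 2 without HFD+RE 4, 2 without the low-count filter and 4170 without HFD+AE 3 and HFD+RE 3, with all of these genes but Hsd3b5 called. Each of these 2 libraries lay nearer to the other exercise group than to its own. Leaving them out therefore widens the difference between the groups by construction.

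Camera called 16 of 36 lists in HFD+RE vs HFD+AE, with no member called over all genes by edgeR. DESeq2 called Igfbp1 (0.00066) and Zbtb16 (0.0023) of gluconeogenesis and glucocorticoid response, Pdk4 (0.0062) of fatty acid oxidation and Nr4a1 (0.0012) of immediate early genes, and edgeR without the low-count filter called Pdk4 (0.049) and Nr4a1 (0.011). Fatty acid oxidation and PPARA targets, with all 30 members at negative log2 changes, was lower in HFD+RE (median -0.39, camera adjusted p = 5.6e-08), as were xenobiotic metabolism (-0.56, 1.3e-06), endothelial cells (-0.63, 7.5e-06), Kupffer cells and macrophages (-0.54, 0.00013), female-biased liver genes (-0.76, 0.00093), gluconeogenesis and glucocorticoid response (-0.36, 0.0044), heat shock (-0.44, 0.0044) and immediate early genes (-0.33, 0.0044). Fibrosis and extracellular matrix (-0.25, 0.0097), cell cycle (-0.22, 0.029), bile acid synthesis and transport (-0.29, 0.032) and pericentral genes (-0.28, 0.032) were lower too. Male-biased liver genes (0.63, 0.012), B and plasma cells (0.30, 0.015), neutrophils (1.95, 0.025) and oxidative phosphorylation (0.34, 0.029) were higher. These 16 lists had an adjusted p = 0.59 to 0.81 with an estimated correlation. When adjusted over the list alone, 3 of 20 xenobiotic genes, 2 of 16 gluconeogenesis genes, 2 of 16 immediate early genes and 1 of 30 oxidation genes fell, and 2 of 18 male-biased genes and 1 of 19 bile acid genes rose.

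Across genes, the log2 changes of HFD+RE vs HFD+AE correlated with gene length at rho = -0.33. The mitochondrial rRNA share was 0.867%, 0.771% and 0.842% in HFD+AE 1, 2 and 3 and 0.685%, 1.11% and 1.71% in HFD+RE 3, 4 and 5, and the globin genes stood at 4.20, 3.36 and 5.66 and at 4.76, 4.11 and 6.05 on the log2 CPM scale. In HFD+RE vs HFD+AE, the calls of fatty acid oxidation, xenobiotic metabolism and endothelial cells held whichever library of these 2 groups was left out. The others were each lost without at least 1 of them. Without HFD+RE 3 bile acid (0.053), gluconeogenesis (0.053), male-biased (0.16), female-biased (0.088), heat shock (0.096), immediate early (0.16), pericentral (0.2) and B-cell (0.073) lists were not called. Without HFD+RE 5 the same held for bile acid (0.15), male-biased (0.06), oxidative phosphorylation (0.15), cell cycle (0.15), pericentral (0.07), Kupffer (0.13), B-cell (0.16, median -0.01) and neutrophil (0.15) lists, and without HFD+RE 4 for oxidative phosphorylation (0.8), fibrosis (0.16) and cell cycle (0.056). Without HFD+AE 3 male-biased (0.068), female-biased (0.11), fibrosis (0.2), cell cycle (0.051), immediate early (0.09), pericentral (0.42) and neutrophil (0.051) lists lost their call. Without HFD+AE 1 bile acid (0.12), oxidative phosphorylation (0.38) and B-cell (0.054) lists did, and without HFD+AE 2 these 3 (0.054, 0.18 and 0.12), male-biased (0.098) and neutrophil (0.054) lists. The number of called lists was 10 without HFD+AE 3, 9 without HFD+RE 3, 9 without HFD+RE 5 and 8 without both HFD+AE 3 and HFD+RE 3, where fatty acid oxidation was not called either (0.084). With the length and GC trend removed, oxidative phosphorylation (0.44), cell cycle (0.062), pericentral (0.11) and neutrophil (0.062) lists were not called. With the length trend alone removed, oxidative phosphorylation (0.41) and pericentral (0.13) lists were not.

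The comparisons HFD+AE vs NC and HFD+RE vs NC asked how far the exercise groups stood from the normal diet. Themis remained higher than in NC, by 3.12 (SE 0.28, adjusted p = 0.00033) in HFD+AE and by 2.66 (SE 0.28, adjusted p = 0.0011) in HFD+RE, as did Osbpl3, an oxysterol-binding protein, by 3.58 (SE 0.33, adjusted p = 0.00033) and 3.71 (SE 0.33, adjusted p = 0.00068). Cyp3a11, the drug-metabolising P450, was lower by -2.94 (SE 0.37, adjusted p = 0.0044) and -3.19 (SE 0.38, adjusted p = 0.003). These calls and those of Sema5b (3.07 and 2.71, adjusted p = 0.0044 and 0.0052) passed in every alternative. Cyp2b9 was higher by 7.68 (SE 1.23, adjusted p = 0.012) and 6.16 (SE 1.16, adjusted p = 0.015), with 8.77, 201 and 8.27 CPM in HFD+RE 3, 4 and 5. Its call was lost without NC 4 in both comparisons (0.066 and 0.072), without HFD+AE 3 in the first (0.055), without NC 2 in the second (0.056), from only the groups compared in the second (0.076) and without the low-count filter in both (0.066 and 0.065). Cyp17a1, a steroid hydroxylase with 9.63 ± 5.83 CPM in NC and 13.2 ± 2.47 CPM in HFD, was higher than in NC by 2.18 in HFD+AE (SE 0.37, adjusted p = 0.014) and by 2.59 in HFD+RE (SE 0.37, adjusted p = 0.0051), the former not without NC 2 (0.058) or HFD+AE 2 (0.063), or from only the groups compared (0.084). Hsd3b5 (-2.02 and -0.91, adjusted p = 0.12 and 0.33) and Cidec (-0.18 and 0.25, adjusted p = 0.83 and 0.58) were not called, and Hsd3b5 was in the first without HFD+AE 1 (0.048). C6 and Elovl3, male-biased genes outside multi-copy families, were called lower in HFD+AE vs NC, and C6 also in HFD+RE vs NC. Without NC 2, C6 stood at -1.56 and -1.14 and was not called (0.077 and 0.13). Its call was also lost without NC 4 in both (0.089 and 0.12) and in other alternatives. That of Elovl3 in the first was lost without HFD+AE 2 (-2.42, 0.063), from only the groups compared (0.06) and without HFD+AE 3 and HFD+RE 3 (0.07).

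In HFD+AE vs NC 253 genes were called, 165 higher and 88 lower, and in HFD+RE vs NC 724, 489 higher and 235 lower. The values did not overlap for 21.9% and 26.1% of genes, where chance gives 10%. Of the 165 and 88 genes, 127 and 70 had changed the same way in HFD vs NC (14 and 6.3 expected if independent), and of the 489 and 235, 395 and 179 (41 and 17 expected). The same NC libraries enter both sides, and over 100 simulations of exercise groups unchanged from NC the highest values were 115 and 65 for HFD+AE (means 41.4 and 19.9) and 292 and 177 for HFD+RE. Part of the excess may come from the shared libraries. The count of HFD+AE vs NC was 131 without HFD 1, 129, 44 and 110 without HFD+AE 1, 2 and 3, and 110 and 58 without NC 2 and NC 4. That of HFD+RE vs NC was 384 without HFD 1, 448 and 1367 without HFD+AE 2 and 3, 3983, 112 and 182 without HFD+RE 3, 4 and 5, and 275, 143 and 456 without NC 2, 4 and 5. Without HFD+AE 3 and HFD+RE 3 together, they were 313 and 5989.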

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

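In this part, the distances between libraries, the removal of the length and GC trend and the fit without HFD+AE 3 and HFD+RE 3 were chosen only after results had been seen.

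The exercise groups differed from each other in 16 gene lists by camera's direct test of HFD+RE vs HFD+AE with a preset correlation, and no list passed with an estimated correlation (adjusted p = 0.59 to 0.81 for these 16). Lower in HFD+RE, by median log2 change, were fatty acid oxidation and PPARA targets (-0.39), xenobiotic metabolism (-0.56), endothelial cells (-0.63), Kupffer cells and macrophages (-0.54), female-biased liver genes (-0.76), gluconeogenesis and glucocorticoid response (-0.36), heat shock (-0.44), immediate early genes (-0.33), fibrosis and extracellular matrix (-0.25), cell cycle (-0.22), bile acid synthesis and transport (-0.29) and pericentral genes (-0.28). Higher were male-biased liver genes (0.63), B and plasma cells (0.30), neutrophils (1.95) and oxidative phosphorylation (0.34). Of the 10 splits of the 6 exercised libraries into 3 and 3, 2 gave as many lists, the real one included, with 16 for the real split and 16 for the highest other; 10 splits cannot give a share under 0.05. The number of called lists was 10 without HFD+AE 3, 9 without HFD+RE 3, 9 without HFD+RE 5 and 8 without HFD+AE 3 and HFD+RE 3.

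For Pdk4 and Zbtb16, each library of 1 exercise group lay above the HFD mean and each library of the other below it. That arrangement was not itself tested. In the direct comparison of HFD+RE with HFD+AE by edgeR, Pdk4 stood at -1.78 (adjusted p = 0.56) and Zbtb16 at -1.99 (adjusted p = 0.52), and neither passed.

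In HFD+RE vs HFD+AE the real split called 0 genes by edgeR (1468 at an unadjusted p under 0.05; 24 by DESeq2), so each of the 10 splits gave as many, and 10 splits cannot give a share under 0.05. The highest other was the split that set HFD+AE 1, HFD+AE 2 and HFD+RE 3 against the rest, with 5032 genes (7161 at an unadjusted p under 0.05). A count so far above the real one points to a structure of the samples that the groups do not describe.

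HFD+AE 3 and HFD+RE 3 each lay nearer to the other exercise group than to their own, and the tables exclude none of the explanations weighed for this. With the length and GC trend removed, the exchanged split still called 2445 genes, so differences in the RNA or library preparation that follow length and GC content may account for part of the structure, and that test does not settle how much. The rank correlation with GC content was 0.49, 0.33 and 0.18 in HFD+AE 3, HFD+RE 4 and HFD+RE 5. It was -0.29, -0.24 and -0.22 in HFD+AE 1, HFD+AE 2 and HFD+RE 3, so its sign divided the libraries as the exchanged split does. An exchange of the labels of these 2 libraries stays open as well: the distance to the other group over that to the own group was 0.49 for HFD+RE 3 (0.35 against 0.72) and 0.81 for HFD+AE 3 (0.53 against 0.66), over 11186 genes, while the other 2 libraries lay 0.28 apart in HFD+AE and 0.41 apart in HFD+RE. A different response of animals within each exercise group, to AE or RE, was not tested and stays open. Without these 2 libraries HFD+RE vs HFD+AE called 4170 genes, a count that the choice of libraries raises by construction.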

How the results depend on the processing

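In this part, the removal of the length and GC trend or the length trend alone, and the fit without HFD+AE 3 and HFD+RE 3, were chosen only after the data had been seen. Counts of called genes depended on the processing far more than directions did. With RLE size factors they were 2903 for HFD vs NC, 8 for HFD+AE vs HFD, 2 for HFD+RE vs HFD, 0 for HFD+RE vs HFD+AE (by edgeR, with 1482 at an unadjusted p under 0.05, and 24 by DESeq2), 237 for HFD+AE vs NC and 718 for HFD+RE vs NC, all within 1.5 times the reported counts, and this scaling moved the median of all genes by at most 0.02. DESeq2 called 2105 genes in HFD+AE vs HFD, 186 in HFD+RE vs HFD, 24 in HFD+RE vs HFD+AE, 792 in HFD+AE vs NC and 1941 in HFD+RE vs NC. Without the low-count filter edgeR called 953 in HFD+AE vs HFD, 43 in HFD+RE vs HFD, 2 in HFD+RE vs HFD+AE and 408 in HFD+AE vs NC. From only the groups compared it called 4928 in HFD vs NC, 649 in HFD+AE vs HFD, 82 in HFD+AE vs NC and 110 in HFD+RE vs NC, and with a 2-fold threshold 1843 in HFD vs NC. With the length and GC trend removed, the counts were 546 in HFD+AE vs HFD, 9 in HFD+RE vs HFD, 534 in HFD+AE vs NC and 1269 in HFD+RE vs NC; with the length trend alone removed they were 77 and 4 in the first 2 of these. Without HFD+AE 3 and HFD+RE 3 they were 6258 in HFD vs NC, 4253 in HFD+AE vs HFD, 5 in HFD+RE vs HFD, 4170 in HFD+RE vs HFD+AE and 5989 in HFD+RE vs NC, and 8 lists were called in HFD+RE vs HFD+AE. With an estimated inter-gene correlation camera called 0 lists in each of the 4 comparisons (2, 5, 8 and 2 at an unadjusted p under 0.05; lists were tested with no other tool). The cause of these differences was not tested.

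HFD and HFD+AE share the replicate numbers 1, 2 and 3. Libraries with the same number correlated at -0.12, 0.11 and 0.09 in their deviations from the group means, and 2 of the 3 pairs correlated best with their own number. Not every pair was above 0.1, the minimum set for reading the numbers as pairs, so a pairing was not established. With these numbers as a replicate block, HFD+AE vs HFD had 2100 called genes, 902 higher and 1198 lower, among them Cidea (-4.38, adjusted p = 0.0012) and Saa1 (-1.97, 0.0012), and 19 lists. That fit held only the libraries of HFD and HFD+AE, which gave 649 called genes without a block. No other comparison was run with a block.

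When each library was left out in turn, the count of called genes ran from 411 (without HFD 3) to 4462 (without HFD+RE 3) in HFD vs NC, and from 0 (edgeR without HFD 1, with 3083 at an unadjusted p under 0.05; DESeq2 called 2105 with all libraries) to 1930 (without HFD+RE 3) in HFD+AE vs HFD. It ran from 2 to 53 (without HFD 2) in HFD+RE vs HFD, from 0 (edgeR, with 536 to 4587 at an unadjusted p under 0.05) to 2 (without HFD+RE 4) in HFD+RE vs HFD+AE, from 44 (without HFD+AE 2) to 373 in HFD+AE vs NC and from 112 (without HFD+RE 4) to 3983 (without HFD+RE 3) in HFD+RE vs NC. The other libraries whose absence moved a count by over 1.5 times are named with their values beside each comparison. The number of called lists ran from 15 to 20 in HFD vs NC, from 15 to 20 in HFD+AE vs HFD, from 19 to 25 in HFD+RE vs HFD and from 9 to 18 in HFD+RE vs HFD+AE, each over the libraries of the groups compared. The share of diet-called genes that moved back in HFD+AE ran from 91.8% to 96.8% when HFD 1, 2 or 3 was left out; no other library was left out singly for it.

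Single genes changed sign only where they had not been called. In HFD vs NC, Cyp7a1 (0.27) ran from -0.29 to 3.39 when single libraries were left out, with -0.23 without NC 2 and -0.29 without NC 4, Cpt1a (0.15) from -0.06 to 0.33, with -0.01 without NC 4 and -0.06 without HFD 2, and Igf1 (-0.06) from -0.21 to 0.26. Igf1 was also at 0.25 with the length and GC trend removed and 0.22 with the length trend alone removed, where Fasn (-0.30) was at 0.03. Cidec ran from -0.39 to 0.08 (without NC 5) in HFD+AE vs NC (-0.18) and was at -0.09 with the length and GC trend removed in HFD+RE vs NC (0.25). The cause was not tested. Of the values of named genes under the alternatives, 798 of 946 kept direction and side of the threshold in HFD vs NC (136 lost the call, 3 gained it), 146 of 195 in HFD+AE vs HFD (37 and 12), 82 of 90 in HFD+RE vs HFD (1 and 7), 66 of 78 in HFD+RE vs HFD+AE (0 and 12), 115 of 130 in HFD+AE vs NC (13 and 1) and 119 of 130 in HFD+RE vs NC (10 and 0). Of 73, 14, 7, 6, 10 and 10 genes in these comparisons, 34, 2, 2, 1, 4 and 7 kept both in each alternative run for them. The pseudocount and filter set out for normalized values were not run, since the values are counts. In the simulations, which drew genes independently, 29% to 40% of genes changed 2-fold were recovered with 3 libraries a group at the depth given. A gene that was not called may therefore still differ, and the share recovered in the real data is not known.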

Other observations

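In this part, the tests of the length and GC trend, of the fit without HFD+AE 3 and HFD+RE 3, of reads shared between gene copies and of a shift to the female pattern, and the comparisons of lymphocyte and globin genes, were chosen only after the results had been seen.

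Some genes of HFD vs NC taken by the naming rule belong to functions only touched on so far. Cyp2a22, a cytochrome P450, rose from 0.975 ± 0.757 CPM (SD, n = 3) in NC to 36.6 ± 7.51 CPM (SD, n = 3) in HFD (log2 change 5.20, SE 0.60, adjusted p = 0.00097). Orm3, an orosomucoid of the acute phase response, rose from 1.82 ± 1.45 to 27.4 ± 4.03 CPM (3.92, SE 0.68, adjusted p = 0.0058). Cyp2c70, which makes the muricholic acids of mouse bile, fell from 431 ± 44.4 to 154 ± 15 CPM (-1.48, SE 0.24, adjusted p = 0.0045). The symbols of these 3 genes place them in multi-copy families, so their single values are treated as uncertain. How many reads each shares with related genes was not measured. Colec11, a collectin used here as a stellate cell marker, rose by 1.18 (SE 0.21, adjusted p = 0.0068), and Ifit1, an antiviral response gene, by 1.69 (SE 0.31, adjusted p = 0.0082). All 5 calls held in each alternative run for single genes. Of the 10 splits of the 6 HFD and NC libraries, 1 gave as many called genes, the real one, with 2851 against 0 by edgeR for the highest other (2005 at an unadjusted p under 0.05, where DESeq2 was not run), and 2 gave as many lists, with 16 against 18. These 10 splits cannot give a share under 0.05.

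Male-biased liver genes were lower in HFD than in NC, with a median log2 change of -2.73 over 18 genes. The tables argue against reads shared between gene copies as the whole cause, since 5 members outside multi-copy families had a mean change of -2.45 in log2 CPM (SE 0.54), 4 of them with a negative log2 change, and the 4 that are not Cyp genes had -3.16 (SE 0.66). These members were picked by symbol, and Serpina12 was left out because its symbol begins like those of the Serpina1 family. They also argue against the length and GC trend as the whole cause, since the median was -2.76 with that trend removed. A shift from the male to the female pattern of liver expression stays open, because the female-biased list had a median of 0.57 and was not called (camera adjusted p = 0.31). An effect of the diet also stays open, as a hypothesis not tested beyond the comparison itself.

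Most genes called in HFD vs NC moved back in the exercise groups, 94.2% of them in HFD+AE and 87% in HFD+RE. With different HFD libraries on each side, the 3 shares were 90%, 84.6% and 87.8% for HFD+AE, so a high share there did not need the same HFD libraries on both sides. The 3 choices used the same HFD+AE and NC libraries. Their shares were not set beside simulated unchanged groups, so no conclusion about the cause is drawn from them. The 91.8% with the length and GC trend removed, as large in 3 of 100 simulated unchanged groups, argues against that trend as the whole cause. The 95.3% without HFD+AE 3 and HFD+RE 3 cannot decide about 1 library apart from its group. HFD+AE 3 lay toward HFD on the first principal component, so leaving it out was likely to raise the share. For HFD+RE the 3 shares were 83%, 48.7% and 86.8%, and the share was 54.8% without HFD+AE 3 and HFD+RE 3, as large in 59 of 100 simulated unchanged groups, so either the shared HFD libraries or 1 library apart from its group may account for its value. With the trend removed the HFD+RE share was 85.5%, as large in 14 of 100 simulated unchanged groups. It kept nearly its size, but unchanged groups reached it too, so no conclusion about the trend is drawn. The diet genes of the 3 choices numbered 488, 3490 and 410. An effect of AE or of RE exercise stays open beside these, and for HFD+RE it cannot be separated from them here. In HFD+AE other measures of the samples moved back as well. The mitochondrial rRNA share was 0.708% to 0.924% in NC, 1.76% to 3.26% in HFD and 0.771% to 0.867% in HFD+AE. The globin genes stood at 4.70, 3.32 and 5.61 in NC, 6.05, 5.29 and 6.46 in HFD and 4.20, 3.36 and 5.66 in HFD+AE on the log2 CPM scale. Whether differences in these measures account for part of the move back was not tested.

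The 10 splits of 6 libraries cannot give a share under 0.05 in the other comparisons either. By edgeR the real split and the highest other called 9 and 0 genes in HFD+AE vs HFD (the other with 3454 at an unadjusted p under 0.05), 2 and 2 in HFD+RE vs HFD, 253 and 0 in HFD+AE vs NC (the other with 1085 at an unadjusted p under 0.05) and 724 and 4 in HFD+RE vs NC, and DESeq2 was not run on splits. As many genes came from 1, 2, 1 and 1 of the 10 splits, the real one included. For lists the real split and the highest other gave 17 and 16 in HFD+AE vs HFD and 23 and 17 in HFD+RE vs HFD, with 1 of 10 splits as large in each.

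Over 24 markers of lymphocytes, the mean log2 CPM was 1.57 (SE 0.67) higher in HFD than in NC, and over 4 globin genes it was 1.39 (SE 0.75) higher. The difference between these 2 was 0.18 (SE 0.53). Over 25 markers of Kupffer and endothelial cells, the mean stood at -1.04 (SE 0.32). These lymphocyte and globin comparisons were also tried before the arrangement of HFD+AE 3 and HFD+RE 3 was picked for weighing.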
